A study of Mus musculus with 2 samples.

How the data were processed

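Total RNA sequencing of neutrophils, labelled as from the spleen of adult male mice, was analysed in 2 libraries, which the labels give as biological replicates 1 and 2 of 1 group. The mice were F1 hybrids of a C57BL/6 mother and a CAST/EiJ father, aged 59 days, and each library was made from 300 ng of RNA with ERCC spike-in controls, per the labels. The libraries were depleted of ribosomal RNA and keep strand, per the labels. Both libraries carry separate biosample labels but the same donor label. Nothing in the labels says that they came from separate animals, so the spread between them, which may be technical, is all that any measure of spread below holds. The p-values of the comparison of the libraries hold counting error alone and leave that spread out; the negative binomial alternative takes its spread from the same 2 libraries.

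The deposited gene table of each library gives an expected count and a TPM per gene. These were estimated from alignments to the transcriptome of mouse build mm10 with annotation release M21, per the file lists deposited with the samples; the aligner, the estimator and their versions are not given in the sources used here. Expected counts are estimated reads that need not be whole, and 16.3% of the counts above 0 in replicate 1 and 16.0% in replicate 2 were not whole. The deposited TPM values are scaled per effective length and to a fixed total over all listed features, ERCC controls included, and a posterior mean TPM stands beside them. The deposited tables give an effective length of 100 bases less than the annotated length, so features of 100 bases or less have TPM of 0. There were 2452 annotated genes of that kind. A transcript table from the same alignments holds 168207 features with an expected count, a TPM and the percent of each gene's TPM that a transcript takes, as deposited. A second deposited transcript table, estimated straight from the reads, holds an estimated count and a TPM for 141864 sequences; the program is not given in the sources used here. Each library has its own tables.

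The gene table lists 55536 annotated genes, all of them matched by identifier to annotation release M21, along with 96 ERCC controls, the phiX174 sequence and 26248 features with numeric names. The annotation gave symbols, gene classes and coordinates on mm10. Estimated reads totalled 18836093 in replicate 1 and 18444369 in replicate 2. The annotated genes other than ribosomal RNA genes held 18060581 and 17609100 reads, and these sums were the offsets of the comparison of the libraries.

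With 1 group of 2 libraries there was no comparison of conditions. Levels are given as TPM per library or as mean and SD of 2 libraries. The libraries were compared gene by gene with an exact two-sided conditional binomial test on expected counts rounded to whole numbers, for genes with a summed count of at least 50, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p of at most 0.05 and a ratio of at least 2-fold, replicate 2 over replicate 1, computed with 0.5 added to each count. This test compares these 2 libraries, not conditions. Fold intervals and intervals of shares are exact Clopper-Pearson intervals at 95%, and they cover counting error only. A fold against a gene with no reads in 1 library was set against a floor of 3 reads in that library. On data simulated from the real rates for the comparison of the libraries (12447 genes tested), 47 of 50 genes changed 2.5-fold and 50 of 50 changed 3-fold were called. In the same data 0 of the 12247 unchanged genes with enough counts to be tested were called. The simulated counts held counting error alone and left out the spread between the real libraries. They therefore do not give the rate of false calls in the real data. Genes changed 1.5-fold were simulated too, but at a threshold of 2-fold they say nothing about the test.

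The biological coefficient of variation was the square root of the common dispersion of the 2 libraries in edgeR 4.0.16 (intercept only, TMM, filterByExpr, R 4.3.3). Tested on counts simulated over 55180 genes with coefficients of 0.1 and 0.2, it returned 0.101 and 0.197. Size factors came from DESeq2 1.42.0. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

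Before the data were examined, 34 gene lists were fixed: lists of neutrophil genes, lists of cell states, 14 lists of other cell types that a spleen preparation could hold, and check lists (sex, housekeeping, RNA without a poly(A) tail). Of their 325 symbols, 324 matched a gene. A symbol with more than 1 identifier took the identifier with more reads. The difference of a list between the libraries is the median log2 ratio of its members with a summed count of at least 10, set among 10000 random lists of the same size drawn from genes in the same 20 bins of mean TPM. It describes these libraries and is no test. After the data were examined, 6 more lists were written: early erythroid, red cell and reticulocyte, late erythroid, bone forming cell, fibroblast and spleen stroma. Their results stand in the closing section. Sets of histone, ribosomal protein, antibody constant and mitochondrial genes were also chosen after their values were seen.

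The rule for naming genes was fixed before the data were examined. It takes the 10 nuclear protein-coding genes with the highest mean TPM; in each list the 3 members with the highest mean TPM, and any member given as absent or low to complete a list; among called genes with a mean TPM of at least 1, the 8 highest and the 8 lowest log2 ratios; all genes of the sex list; and the 5 genes that differ most each way between the 2 transcript tables among those with a mean TPM of at least 5 in either. Some genes that the rule takes, and some called members of lists, are not named in the text or drawn in the figures; the medians and counts of lists include them. Other genes named in the text were chosen after their values were seen, as members of a list that was called or as examples of a gene class.

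Alternatives covered other detection limits, pseudocounts of 0.1, no filter, protein-coding genes alone, TMM factors, DESeq2 size factors, the ERCC total as the offset, a summed count of at least 10, a ratio of at least 1.5-fold, the second transcript table, a negative binomial test in edgeR, shares of TPM, and each replicate left out. Genes annotated as ribosomal RNA were left out of the comparison of the libraries because their depletion varies from library to library. Reads of the CAST/EiJ allele were counted against a C57BL/6 reference, and the share of reads lost that way was not measured.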

Results

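Neutrophils are short-lived phagocytes of the innate immune system that kill microbes with granule proteins and oxidants. The study profiled primary cells labelled as neutrophils from the spleen of male F1 hybrid mice (C57BL/6 mother, CAST/EiJ father) aged 59 days. Total RNA was sequenced after ribosomal RNA depletion in 2 libraries labelled as biological replicates of 1 group. The libraries held 18836093 estimated reads in replicate 1 and 18444369 in replicate 2. No other group was labelled, so the data answer which genes these cells express and how far the libraries differ. At this depth, 11921 of 55536 annotated genes reached a TPM of at least 1 in both libraries. By the posterior mean TPM that number was 16189.

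The calprotectin genes were the highest nuclear protein-coding genes. S100a9 (ENSMUSG00000056071.12, chromosome 3, 90692632 to 90695721 on mm10) stood at 23224 ± 1067 TPM and its partner S100a8 (ENSMUSG00000056054.9, chromosome 3, 90668978 to 90670035) at 19295 ± 1214 TPM (SD, n = 2). Next came Actb at 7178 ± 253 TPM and the lysozyme gene Lyz2 at 6721 ± 297 TPM. The other genes among the 10 highest were the granule genes Ngp (6574 ± 173 TPM), Ltf (4452 ± 5.02 TPM), Lcn2 (3547 ± 83.0 TPM) and Camp (2609 ± 171 TPM), with Retnlg (3919.8 ± 442 TPM) and Tmsb4x (3217 ± 19.3 TPM), all SD with n = 2. All 20 members of the neutrophil identity list reached a TPM of 1 in both libraries, with list medians of 341 TPM in replicate 1 and 279 TPM in replicate 2. On the log2(TPM + 1) scale the list median exceeded that of 119 genes of other cell types by 6.54 ± 0.165 (SD, n = 2), a 93.2-fold difference. That pool mixes lists from NK cell medians of 0.10 and 0.12 TPM to monocyte medians of 119 and 105 TPM. The fold thus depends on which cell types were listed, and it is far smaller against the monocyte list alone.

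Genes of the secondary granules, which neutrophils make as myelocytes, were the highest of the granule lists. Their list median was 2488 TPM in replicate 1 and 2730.3 TPM in replicate 2, led by Ngp (chromosome 9, 110419747 to 110423012), Ltf (chromosome 9, 111019271 to 111042767) and Lcn2 (chromosome 2, 32384633 to 32388252). The gelatinase granule list had medians of 428 and 371 TPM, with Mmp9 at 864 ± 57.1 TPM, Mmp8 at 542 ± 62.5 TPM and Hp at 445 ± 16.4 TPM (SD, n = 2). Genes of the primary granules, which are transcribed in promyelocytes, were lower but present. Their medians were 75.5 and 101 TPM, with the myeloperoxidase gene Mpo at 411 ± 69.6 TPM, Prtn3 at 238 ± 37.8 TPM (SD, n = 2) and Elane at 239 and 321 TPM in replicates 1 and 2. The secondary granule median exceeded the primary granule median by 4.88 ± 0.196 on the log2(TPM + 1) scale (SD, n = 2), a 29.6-fold difference. With means in place of medians that difference was 3.71, a value that gives more weight to Olfm4 and Itgb2l, at 66.0 and 175 TPM.

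Receptors and enzymes of neutrophil function were expressed at high levels. All 8 NADPH oxidase genes reached a TPM of 1, with medians of 420.3 and 404 TPM and the subunit genes Rac2 (691 ± 25.6 TPM), Ncf1 (576 ± 29.9 TPM) and Cybb (527 ± 17.5 TPM) highest. All 15 chemoattractant and adhesion receptor genes did so as well, with medians of 182 and 147 TPM, led by the integrin genes Itgb2 (378 ± 19.2 TPM) and Itgam (355 ± 18.1 TPM) and by Cxcr4 (272 ± 28.0 TPM). In the mature neutrophil list (medians of 248 and 219 TPM) the highest were Msrb1 at 519.9 ± 53.2 TPM, the G-CSF receptor gene Csf3r at 471 ± 60.1 TPM and Ccl6 at 371 ± 12.2 TPM. Pattern recognition genes had medians of 15.1 and 15.2 TPM. Among them were Nlrp3 at 137 ± 0.0778 TPM, Clec7a at 108 ± 7.20 TPM and Tlr13 at 64.9 ± 5.93 TPM. Fc receptor genes had medians of 45.3 and 45.7 TPM, with Fcer1g at 483 ± 38.5 TPM, Fcgr3 at 184 ± 3.44 TPM and Fcgr2b at 45.5 ± 0.304 TPM. Fcgr1 was the only 1 of these 5 under a TPM of 1 in a library, at 0.85 in replicate 1 and 1.45 in replicate 2. The granulocyte transcription factor list had medians of 60.4 and 68.2 TPM, led by Klf2 (814 ± 219 TPM), Mxd1 (323 ± 46.1 TPM, SD, n = 2) and Spi1 (228 TPM in replicate 1 and 209.9 TPM in replicate 2).

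**Figure D1:**
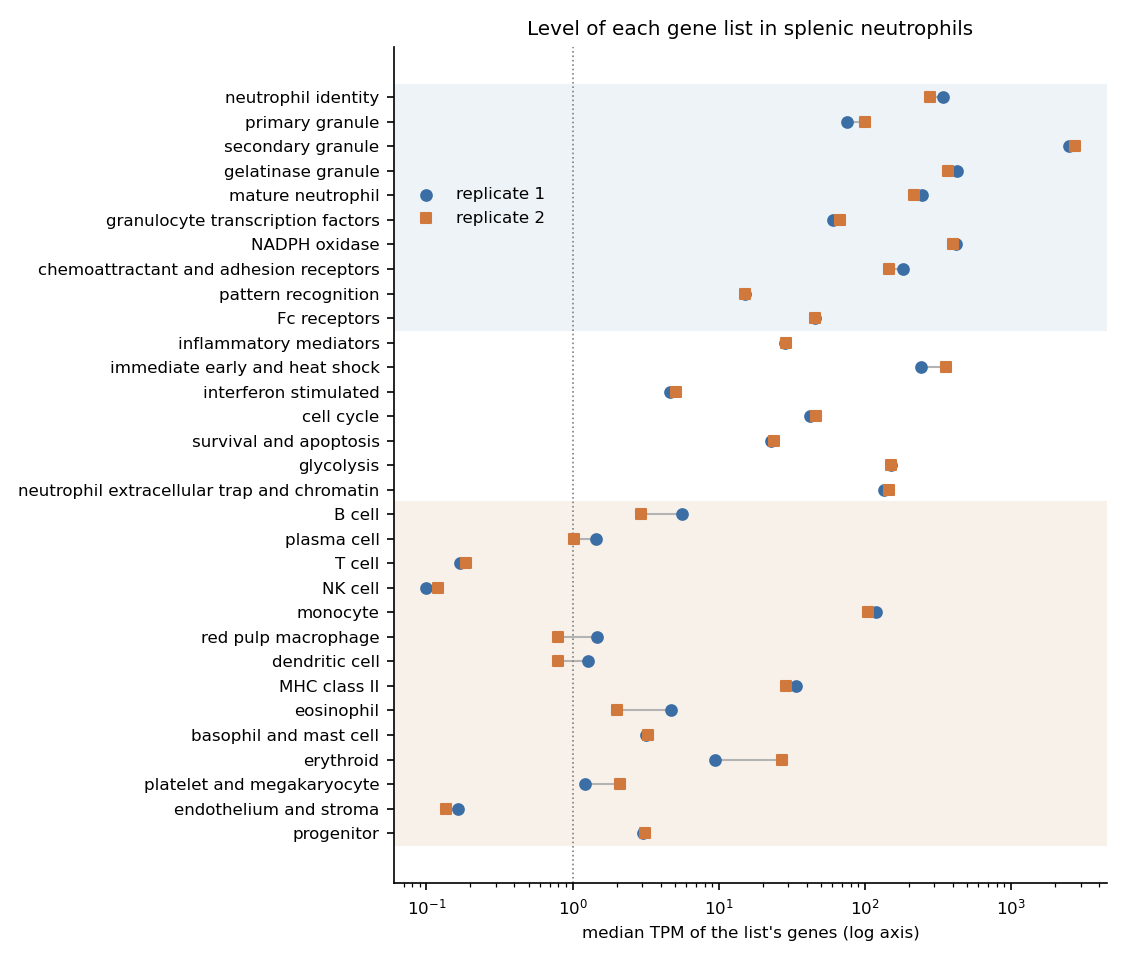
Median TPM of each gene list (log axis) in replicate 1 (circles) and replicate 2 (squares), with neutrophil lists shaded blue and lists of other cell types shaded orange; the dotted line marks a TPM of 1. The check lists are not drawn. Among the lists drawn, secondary granule genes lie highest, at 2488 and 2730.3 TPM, and T cell, NK cell and stromal lists lie under 1 TPM in both libraries.

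Immediate early genes, which cells switch on within minutes of a stimulus or of handling, stood at high levels. Their list, which includes heat shock genes, had medians of 244 TPM in replicate 1 and 358 TPM in replicate 2, with Fos at 1570 ± 433 TPM, the phosphatase gene Dusp1 at 895 ± 179 TPM and Zfp36 at 589 ± 71.0 TPM (SD, n = 2). Inflammatory mediator genes had medians of 28.4 and 29.0 TPM, with the chemokine gene Cxcl2 at 159 ± 53.0 TPM, Il1b at 158 ± 51.1 TPM and Osm at 144 ± 10.5 TPM. In that list 12 of 17 members reached a TPM of 1 in both libraries, and Il12b had no reads in either, which allows up to 3 reads per library. Cell cycle genes were expressed, with medians of 42.1 and 46.6 TPM, Top2a at 127 ± 16.3 TPM, Mki67 at 122 ± 10.1 TPM and Pcna at 119 ± 19.8 TPM. Interferon stimulated genes had low medians of 4.67 and 5.09 TPM, with members such as Ifitm3 (249.7 ± 11.1 TPM) and Irf7 (12.6 and 14.7 TPM) above them. Glycolysis genes had medians of 151 and 151 TPM, with Gapdh at 659.5 ± 16.6 TPM, Pkm at 498 ± 17.8 TPM and Gpi1 at 349 ± 3.45 TPM. In the survival and apoptosis list (22.8 and 24.1 TPM) Mcl1 led at 285 ± 9.90 TPM, followed by Bak1 at 35.9 ± 3.06 TPM and Bcl2l11 at 32.2 ± 2.03 TPM. The list for extracellular traps and chromatin had medians of 135 and 147 TPM, with the peptidylarginine deiminase gene Padi4 at 198 ± 4.12 TPM, Lmnb1 at 165 ± 7.75 TPM and Hmgb1 at 141 ± 8.72 TPM.

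Markers of most other cell types were low, with exceptions. Monocyte genes reached medians of 119 and 105 TPM, with Fn1 at 838 ± 97.3 TPM, Ly6c2 at 471 ± 4.55 TPM and F13a1 at 288 ± 31.1 TPM (SD, n = 2). MHC class II genes had medians of 34.0 and 29.1 TPM, led by Cd74 (125 ± 2.97 TPM), H2-Ab1 (39.1 ± 0.516 TPM) and H2-Aa (34.7 and 32.6 TPM). Erythroid genes had medians of 9.50 and 27.2 TPM, the highest being the globin genes Hba-a1 (527 and 569.7 TPM), Hbb-bs (357 ± 59.9 TPM) and Hba-a2 (236 ± 67.9 TPM). B cell genes had medians of 5.57 and 2.96 TPM, with the antibody chain genes Igkc (159 ± 45.2 TPM), Ighm (146 ± 29.8 TPM) and Iglc2 (17.5 ± 1.28 TPM) highest. The plasma cell list stood at 1.44 and 1.02 TPM, with Xbp1 at 70.8 ± 1.39 TPM, Jchain at 12.4 ± 2.55 TPM and Mzb1 at 1.44 ± 0.205 TPM. Eosinophil genes had medians of 4.70 and 2.02 TPM, among them Prg2 at 45.6 ± 12.5 TPM, Epx at 6.71 ± 1.99 TPM and Siglecf at 4.66 ± 0.219 TPM. Basophil and mast cell genes had medians of 3.21 and 3.27 TPM, yet the basophil protease genes Prss34 and Mcpt8 reached 55.4 ± 1.18 and 55.3 ± 0.884 TPM, with Cpa3 at 3.48 ± 0.0778 TPM.

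The remaining lists of other cells had medians under 4 TPM. Progenitor genes had medians of 3.03 and 3.15 TPM, with Myb at 28.9 ± 4.83 TPM, Kit at 7.29 ± 2.82 TPM and Cd34 at 4.11 ± 0.304 TPM (SD, n = 2). Platelet and megakaryocyte genes had medians of 1.22 and 2.10 TPM, led by Pf4 (7.80 ± 0.502 TPM), Ppbp (6.72 and 6.07 TPM) and Itga2b (5.03 ± 0.453 TPM). Red pulp macrophage genes had medians of 1.48 and 0.79 TPM, and the iron handling genes Slc40a1 (53.1 ± 0.863 TPM) and Hmox1 (24.3 ± 1.58 TPM) stood above Adgre1 (16.5 ± 3.58 TPM). Dendritic cell genes had medians of 1.28 and 0.80 TPM, with Itgax at 9.09 ± 4.71 TPM, Cd209a at 4.13 ± 0.120 TPM and Flt3 at 2.28 ± 0.0283 TPM. T cell genes had medians of 0.17 and 0.18 TPM; Cd3d alone was high, at 42.5 ± 4.72 TPM, and Trac and Lck both averaged 0.665 TPM. NK cell genes had medians of 0.10 and 0.12 TPM, with Klra8, Klrd1 and Klrb1c at 0.465, 0.250 and 0.145 TPM on average. In the endothelium and stroma list (0.165 and 0.135 TPM) the collagen genes Col1a1 and Col1a2 averaged 60.7 ± 50.5 and 32.0 ± 25.1 TPM and Pecam1 4.64 ± 0.170 TPM, while Madcam1, Ccl19, Ccl21a and Cxcl13 had no reads in either library.

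The sex genes matched the male label. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 48.5 ± 3.22, 23.9 ± 1.41, 9.35 ± 0.552 and 6.81 ± 0.255 TPM (SD, n = 2), and Xist, the RNA that silences an X chromosome in females, averaged 0.03 TPM. Housekeeping genes had medians of 529 and 512 TPM, with Actb, Tmsb4x and Eef1a1 (1592 ± 27.6 TPM) highest.

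RNA species without a poly(A) tail made up much of the TPM of these total RNA libraries. The identical copies of the signal recognition particle RNA, Rn7s1 and Rn7s2 (chromosome 12, 69159295 to 69159594 and 69361182 to 69361481), each stood at 154140 ± 1648 TPM and together held 30.8% of TPM but 6.15% ± 0.128 of reads. The transcription regulator RNA Rn7sk (chromosome 9, 78175303 to 78175633) followed at 56078 ± 1512 TPM. The list of non-polyadenylated or nuclear RNA had medians of 3983 and 4332 TPM. Protein-coding genes held 79.7% ± 1.02 of reads and 46.8% ± 0.127 of TPM (SD, n = 2). The mitochondrial genome took 4.37% of reads in replicate 1 (95% interval 4.36% to 4.38%) and 4.77% in replicate 2 (4.76% to 4.78%), most of it in mitochondrial ribosomal RNA. Annotated nuclear ribosomal RNA genes held 0.000466% and 0.000618% of reads, with exact intervals of 0.000375% to 0.000576% and 0.00051% to 0.000742%. The lincRNA genes Gm26917 and Gm42418, side by side on chromosome 17, held far more, 3.50% of reads in replicate 1 (3.49% to 3.51%) and 4.72% in replicate 2 (4.71% to 4.73%), with Gm26917 at a 1.39-fold ratio. Whether their reads derive from ribosomal RNA repeats was not tested, so the share of annotated ribosomal RNA genes may understate ribosomal RNA. Being annotated as lincRNA, both genes stayed in the comparison of the libraries and in its offsets. The 10 highest genes by reads took 18.3% and 19.4% of reads (18.3% to 18.3%, and 19.4% to 19.4%). ERCC controls took 0.261% (0.258% to 0.263%) and 0.274% (0.271% to 0.276%), and 48 of 96 controls had reads in both libraries. All features share 1 fixed TPM total, so TPM values here are not to be set against those of poly(A)-selected libraries.

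**Figure D2:**
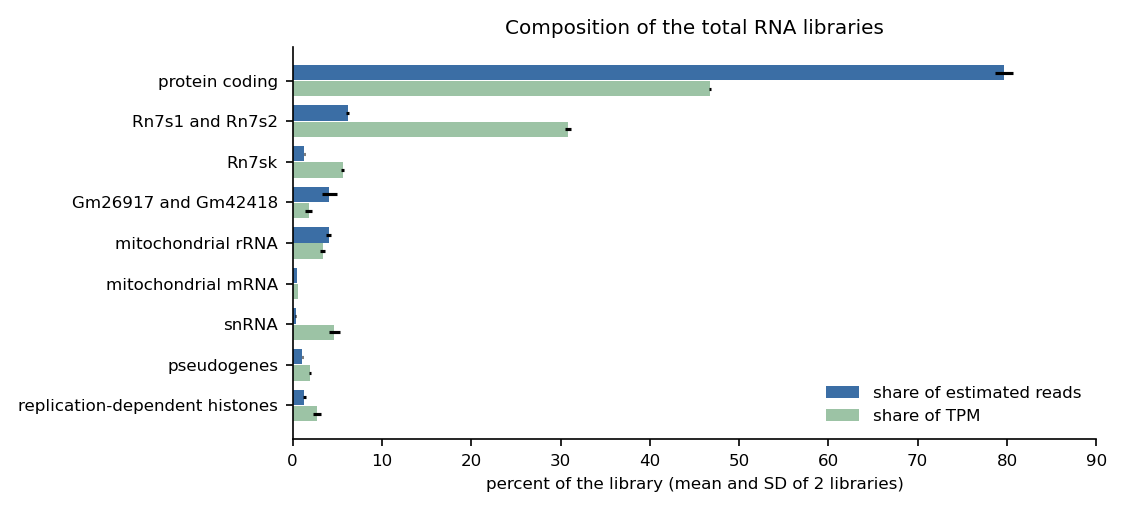
Share of estimated reads (blue) and of TPM (green) by gene class, as mean and SD of 2 libraries, in percent on a linear axis from 0. Rn7s1 and Rn7s2 take 6.15% of reads but 30.8% of TPM, because TPM divides reads by length.

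Most genes agreed closely between the replicates. Across 12532 genes with a mean TPM of at least 1, log2(TPM + 1) correlated with Pearson r = 0.974 and Spearman rho = 0.974; this is a correlation across genes, which are not independent replicates. Of 12434 genes with a summed count of at least 50, 93.0% differed by less than 1.5-fold, and the median absolute log2 ratio was 0.14. Genes such as Ltf (log2 ratio 0.00), Cybb (-0.01), Nlrp3 (0.00) and Cd74 (-0.01) had nearly equal counts for their totals. The biological coefficient of variation was 11.6% over 13667 genes. Over all tested genes the counts differed by more than sampling noise, with a chi-square of 14.5 per degree of freedom; whether that spread lies between animals or in library preparation was not tested.

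Of the erythroid genes 7 were called higher in replicate 2, and of the B cell genes 4 were called lower there. In the erythroid list, 7 of 12 tested genes were higher in replicate 2 and passed the test, and the same number passed when adjusted over the list alone. Among them were Car1 (3.81-fold, 95% counting interval 3.08 to 4.76), Epb42 (3.63-fold), the transcription factor genes Gata1 (3.59-fold) and Klf1 (3.31-fold), Car2 (3.57-fold) and the anion exchanger gene Slc4a1 (3.15-fold, interval 2.88 to 3.44). The other 5, the globin genes and the heme synthesis gene Alas2, stayed under 2-fold and were not called, with log2 ratios from -0.61 for Hba-a2 to 0.09 for Hba-a1. By the exact binomial test Hba-a2 and Hbb-bs (-0.37) were lower in replicate 2 at adjusted p of 1.5e-37 and 4.25e-25. Hba-a1 was higher there at 7.02e-03 by the same test. Its log2 ratio was -0.0084 in the second transcript table, so that rise depends on the table. Hba-a2 and Hbb-bs stood at -0.69 and -0.36 in the second transcript table. The list's median log2 ratio of 1.69 lay above every one of 10000 random lists. In the B cell list, 4 of 10 tested genes were lower in replicate 2 and passed, among them Cd79a (log2 ratio -1.26), Pax5 (-1.18) and Ms4a1 (-1.18), and 4 did so when adjusted over the list alone. Pax5 differed less in TPM, at 5.82 in replicate 1 and 4.60 in replicate 2. In the second transcript table it stood at 5.63 and 4.16 TPM. The B cell list's median of -0.96 lay below every random list. The plasma cell list had a median of -0.53 (percentile 0.79), with Sdc1 the 1 gene of 4 tested that passed (-1.49), and the eosinophil list one of -0.43 (percentile 0.49), with Ear6 the 1 of 5 that passed (-1.18).

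**Figure D3:**
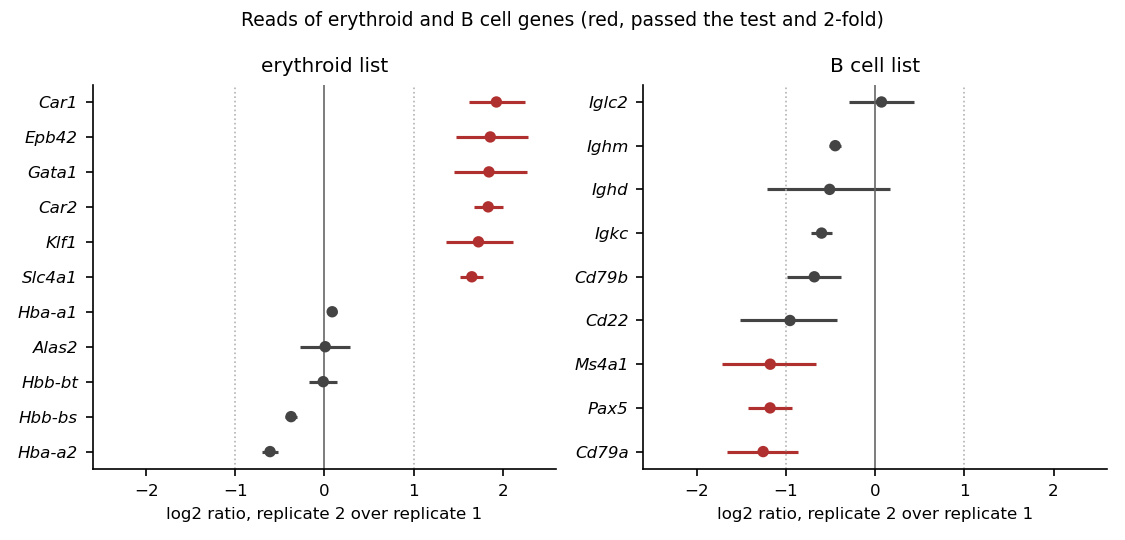
Log2 ratio of reads, replicate 2 over replicate 1, for erythroid (left) and B cell (right) genes with a summed count of at least 50, not all of them shown; points are ratios, bars are 95% counting intervals, and red marks genes that passed the test at 2-fold (dotted lines). The red erythroid genes shown lie between 1.65 and 1.93 and the globin genes and Alas2 between -0.61 and 0.09.

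No gene of the primary granule, cell cycle, mature neutrophil, identity, receptor and pattern recognition lists was called, and only the medians of these lists are described. All 7 primary granule genes had ratios above 0 (median log2 ratio 0.36, percentile 99.99), among them Elane (0.41) and Mpo (0.36). All 12 cell cycle genes also had ratios above 0 (median 0.29), among them Mcm2 (0.48) and Pcna (0.36). In contrast, all 10 mature neutrophil genes had ratios below 0 (median -0.23), as did 18 of 20 neutrophil identity genes (median -0.24) and 14 of 15 chemoattractant and adhesion receptor genes (median -0.18, percentile 0.03). Of the 13 pattern recognition genes, 11 had ratios below 0 (median -0.19, percentile 0.07). None of these genes reached 2-fold, so 0 were called over all genes tested and 0 adjusted over the list alone.

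The immediate early and heat shock list had a median ratio above 0 and the inflammatory list one below 0, with 2 genes called in the first and 0 in the second. Of the 14 immediate early and heat shock genes, 12 had ratios above 0 (median 0.31, above every random list). The heat shock genes Hspa1b (4.51-fold, interval 3.77 to 5.45) and Hspa1a (3.45-fold, 3.06 to 3.89) were higher in replicate 2 and passed the test, over all genes and adjusted over the list alone. Fosb (1.92-fold), Jun (1.70-fold) and Fos (1.45-fold) lay under the 2-fold threshold. Of 14 inflammatory mediators with enough reads, 12 had ratios below 0 (median -0.70, below every random list), among them Ptgs2 (-0.92), Cxcl2 (-0.71) and Il1b (-0.71), and 0 of 12 tested were called. From the second transcript table that median was -0.39, and the eosinophil median -0.67. Interferon stimulated genes had a median of 0.27 (percentile 99.86), and Ifit3 was the 1 gene of 15 tested that passed, at 2.26-fold.

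In the remaining lists the median ratio lay inside the central 95% of random lists. These medians were 0.04 for secondary granule, -0.15 for gelatinase granule, 0.01 for granulocyte transcription factors, -0.03 for NADPH oxidase, -0.05 for Fc receptors, 0.06 for survival and apoptosis, -0.04 for glycolysis and -0.08 for extracellular traps and chromatin. For other cell types they were -0.39 for T cell, -0.07 for monocyte, -0.23 for red pulp macrophage, -0.11 for dendritic cell, -0.14 for MHC class II, 0.01 for basophil and mast cell, 0.12 for platelet and megakaryocyte, 0.14 for endothelium and stroma and 0.21 for progenitor. The check lists gave -0.13 for sex, 0.03 for housekeeping and 0.10 for non-polyadenylated or nuclear RNA. From the second transcript table, medians that moved by over 1.5 times but stayed inside the random range were -0.24 for T cell, 0.01 for platelet and megakaryocyte, 0.08 for progenitor, 0.26 for endothelium and stroma, -0.04 for granulocyte transcription factors, 0.01 for survival and apoptosis, -0.02 for glycolysis and 0.05 for non-polyadenylated or nuclear RNA. With 10 counts added the T cell median was -0.26. Called genes in these lists were Col1a1 (3.84-fold, interval 3.68 to 4.01) and Col1a2 (3.58-fold), higher in replicate 2, and Bcl2a1b (-1.20) and Gp5 (-1.12), lower in replicate 2. The red pulp macrophage median lay at the lower edge of the random range, and below it under 2 other settings, at -0.23 with 10 counts added and -0.44 from the second transcript table. The NK cell list had 1 member with enough reads and no median was placed.

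**Figure D4:**
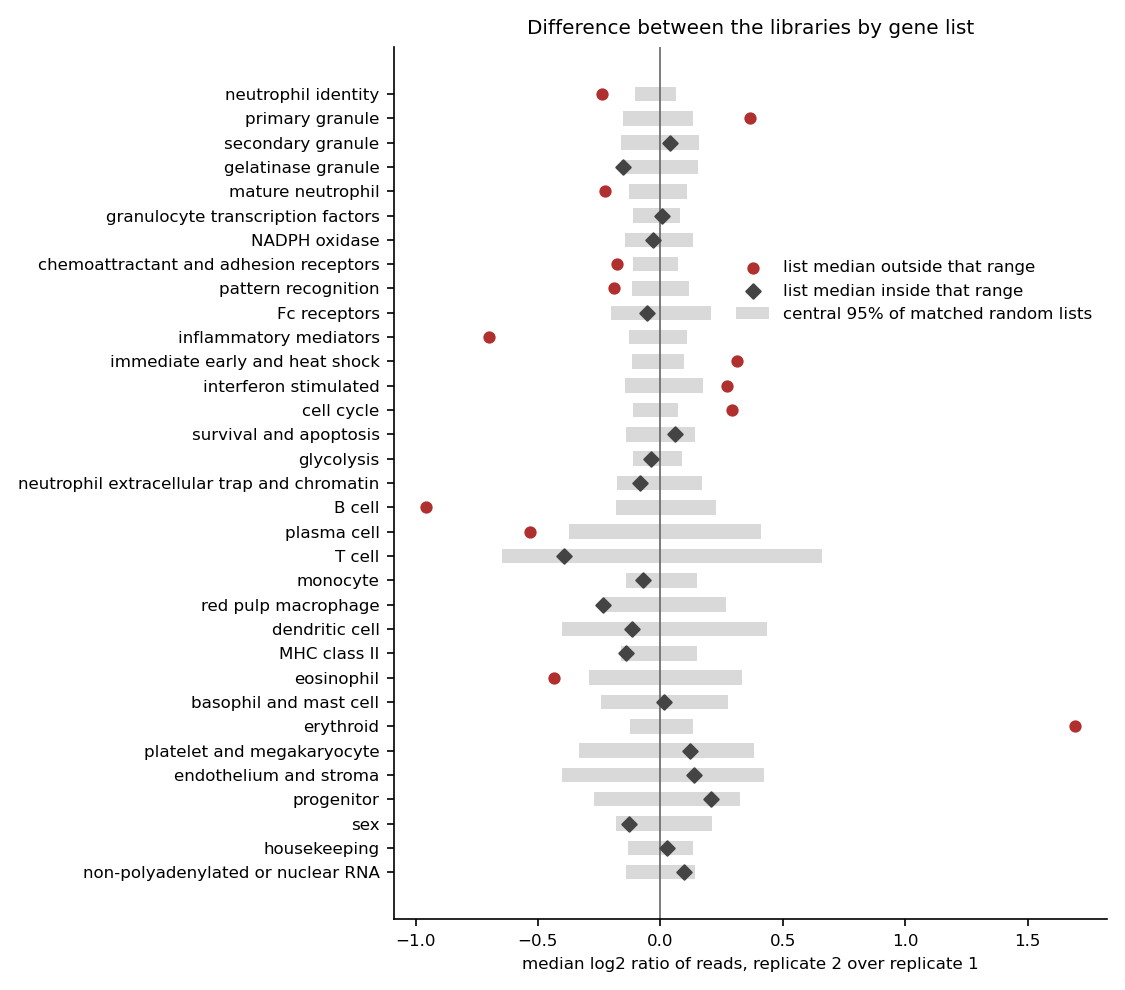
Median log2 ratio of reads, replicate 2 over replicate 1, of 33 gene lists (points), with the central 95% of 10000 random lists matched on size and mean TPM (grey bars). The medians of 5 lists lie above that range and of 8 below it; the erythroid list is highest at 1.69 and the B cell list lowest at -0.96.

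Over all genes, 280 of 12434 tested were called, with 195 higher in replicate 2 and 85 lower, by the exact binomial test with Benjamini-Hochberg adjustment. A further number passed at adjusted p alone: 3027 genes in all lay at or under 0.05, most of them with ratios under 2-fold. Protein-coding genes made up 217 of the calls (170 higher and 47 lower in replicate 2), pseudogenes 33, small RNA genes 7 and antibody constant genes 4. A negative binomial test in edgeR called 181 genes; it sets 1 library against 1 with a dispersion estimated from the same 2 libraries, so it gives no separate support for these calls.

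The 8 highest ratios held 5 protein-coding genes and 3 noncoding ones. The protein-coding genes were Sh2d4a (6.30-fold), Smim1 (6.20-fold), Sec14l2 (5.95-fold), the amino acid transporter gene Slc38a5 (5.82-fold) and Gm49356 (5.73-fold). These 5 had from 7.82 to 32.0 reads in replicate 1 and from 47.1 to 184 in replicate 2. The snRNA gene Gm24497 (chromosome 1, 72244213 to 72244403) had 1.28 reads in replicate 1 and 1758 in replicate 2, a ratio with a counting interval of 323 to 71260. Gm24924 and Gm6565 had no reads in replicate 1 and 150 and 57.7 in replicate 2, at least 51.3-fold and 19.8-fold higher against a floor of 3 reads. In the second transcript table Gm49356, Gm24497, Gm24924 and Gm6565 had no reads in either library, and Sh2d4a, Smim1, Sec14l2 and Slc38a5 had log2 ratios of 2.23, 2.47, 2.48 and 2.59.

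The 8 lowest ratios were mostly pseudogenes. Gm13394, Gm5966 (ENSMUSG00000116963.1), Rps27a-ps2 and AC124512.1 had no reads in replicate 2, which put them at least 72.8-fold, 45.8-fold, 31.5-fold and 16.9-fold lower there against the same floor. A second gene of the symbol Gm5966 at the same position had 92.7 and 167 reads. Nutf2 (log2 ratio -4.31), Gm27517 (-3.22) and Gm15429 (-2.44) followed, and the antibody gene Ighg3 (-4.30) fell in the same range. Of these, Gm5966, Nutf2 and Gm15429 had log2 ratios of 0.0412, 0.31 and 0.15 in the second transcript table. Rps27a-ps2 and Gm27517 had no reads there in either library, AC124512.1 stood at 0.0501 and 0.0572 TPM, and Gm13394 at 0.333 TPM in replicate 1 and 0 in replicate 2. Other protein-coding genes lower in replicate 2, chosen after their values were seen, were the B cell genes Cd38 (-2.40), Cd72 (-1.65), Fcrla (-1.64), Spib (-1.44) and Bach2 (-1.36), and the chemokine gene Cxcl12 (-2.05). The antibody genes Ighg1 (-2.34), Ighg2c (-1.38) and Ighg2b (-1.26) passed as well, making 4 of 11 antibody constant genes tested with Ighg3, while Igha (0.21) did not reach 2-fold.

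The 2 transcript tables gave close levels for protein-coding genes and different ones for small RNA genes and pseudogenes. Summed per gene, TPM correlated with Spearman rho = 0.869 in both replicates over 13257 and 13189 genes, and the median absolute log2 difference was 0.20 in replicate 1 and 0.17 in replicate 2. For protein-coding genes rho was 0.977 in both, and for pseudogenes and small RNA genes it was -0.17 and -0.20, again across genes. The genes placed lowest in the second table were the snRNA copies Gm23444, Gm23472, Gm24265 and Gm24407 and the ribozyme gene Rmrp. They averaged 7580.1, 7580.1, 3741, 3332 and 5187 TPM in the first and their log2 differences, second less first, ran from -12.89 to -11.70. The second table lists these 5 with no reads in either library, so the 1 TPM added before the log sets these differences; a second gene of the symbol Rmrp (ENSMUSG00000115420.1) holds reads there. Those placed highest were Gm19220, Gm42674, Gm47283, Gm38356 and Gm7336, which lay 11.10, 7.42, 7.35, 6.37 and 6.16 log2 units above the first table, where 4 of the 5 had no reads.

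The leading transcript differed between the tables for S100a8, and for S100a9 in replicate 1, among the 10 highest genes, and shares differed for Actb, Ltf and Lcn2. Lyz2, Ngp, Retnlg and Camp have 1 annotated transcript. Actb-201 held 93.3% and 94.9% of the TPM of Actb in the first table and 55.6% and 62.2% in the second. Tmsb4x-201 held 95.2% and 95.3% in the first table and 98.6% and 98.7% in the second. Lcn2-201 held 99.3% and 99.4% in the first and 70.2% and 69.3% in the second, and Ltf-201 55.5% and 56.3% against 31.6% and 34.0%. For S100a8 the coding transcript S100a8-201 held 97.7% and 96.9% in the first table, and the retained-intron transcript S100a8-202 held 57.4% and 55.3% in the second. For S100a9 the leading transcript was S100a9-201 in the first table (74.7% and 76.1%), and in the second S100a9-202 in replicate 1 (98.1%) but S100a9-201 in replicate 2 (88.8%).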

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

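Reads outside the annotated genes and spike-in controls appeared in both libraries at low levels. The phiX174 sequence, a control added to sequencing runs, held 48 reads in replicate 1 and 45 in replicate 2, above the 3 reads that a count of 0 allows. The 26248 features with numeric names together held 25.99 estimated reads in replicate 1 and 14.95 in replicate 2, also above that limit, and what they stand for is not given in the sources used here.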

How the results depend on the processing

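The alternatives that sum genes with identical transcripts and that leave out erythroid, pseudogene and small RNA genes were chosen after seeing the data; all others were planned. How far a value had to shift to count as moved was settled once the values were visible. Leaving out a replicate was not possible for the comparison of the libraries, and no paired analysis was possible because there was 1 group. The number of genes called was 280 and stayed between 220 and 299 under TMM factors, size factors, the ERCC total, protein-coding genes alone, the second table and both later alternatives. It was 543 (329 higher and 214 lower in replicate 2) with a summed count of 10, because more genes were tested, and 608 (379 and 229) at 1.5-fold, because the threshold was lower. The negative binomial test called 181, with 42 lower, with a dispersion taken from the same 2 libraries that it compares. Protein-coding genes alone gave 44 lower, and 80.0% of those calls were higher in replicate 2 against 69.6% over all genes; the second table shared 183 calls with the main result. From that table, Gm5966, Nutf2 and Gm15429 turned to log2 ratios of 0.0412, 0.31 and 0.15; the cause was not tested here. Pearson r was 0.941 with a pseudocount of 0.1, 0.986 without a filter, 0.987 for protein-coding genes and 0.981 in the second table, and Spearman rho in the last 3 was 0.938, 0.986 and 0.976. The coefficient of variation was 12.9% without a filter and 10.9% for protein-coding genes. Genes detected, 11921 in the main result, were 16230 at a TPM of 0.1 and 13735 at a count of 10. They were 16189 by the posterior mean TPM and 12826 in the second table. Neutrophil identity over other cell types was 6.99 with a pseudocount of 0.1, 6.16 with means, 6.79 with TPM of protein-coding genes alone and 6.84 in the second table, and 6.43 to 6.66 without a replicate. Secondary over primary granule was 3.71 with means. As shares of TPM, protein-coding genes took 46.8%, nuclear ribosomal RNA genes 0.00607%, mitochondrial genes 3.97%, the 10 highest genes 45.1% and ERCC controls 0.361%, since TPM divides by length. Between the transcript tables, rho was 0.818 without a filter and 0.977 for protein-coding genes. Elsewhere the cause of a shift was not tested. Genes with few reads set the limit of depth: 12434 of 55536 genes had enough reads to be tested.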

Other observations

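Tests chosen only after the result was seen were the globin and Alas2 test, the 6 later gene lists as such, the histone, ribosomal protein and Cd3d results, the count of 50 reads asked of bone genes, and the restriction of the last test to calls with enough reads in the second table. The level of Col3a1, 1 of 10 fibroblast genes, had been seen before that test.

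Replication-dependent histone genes, whose RNAs lack a poly(A) tail and peak in S phase, were abundant. Of 67 such protein-coding genes, 63 reached a TPM of 1 in both libraries, and together they held 1.32% ± 0.188 of reads (SD, n = 2). Hist2h2aa2 (1656 ± 260.5 TPM), Hist1h4k (1311 ± 325 TPM) and Hist1h4f (1292 ± 215 TPM) were highest. Their ratios went the way of the cell cycle list: 62 of 64 lay above 0, with a median log2 ratio of 0.32, above every one of 10000 random lists, and 2 were called, Hist3h2ba (1.92) and Hist2h2aa1 (2.36). In the second table the ratio of Hist2h2aa1 was 0.43, at 748 and 973 TPM against 4.52 and 23.8 TPM in the first, so its call depends on the table. Ribosomal protein genes had a median log2 ratio of 0.12, with 72 of 80 above 0 and 0 of 79 called.

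Cd3d was expressed without its partners. It averaged 42.5 TPM, from 745 and 559 reads, while Cd3g had 8 and 2 reads and Cd3e had 4 and 0. In the second table the retained-intron transcript Cd3d-203 held 62.7% of its TPM in replicate 1 and 64.3% in replicate 2. In the first table the leading transcript was the coding Cd3d-201 in replicate 1 and the coding Cd3d-202 in replicate 2 (55.3%). For Il1r2, a decoy receptor gene, the leading transcript in the first table was Il1r2-204, annotated for nonsense-mediated decay, in replicate 1 (38.02%), and the coding Il1r2-203 in replicate 2 (49.2%).

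The 7 erythroid genes called higher in replicate 2 raise the question of whether that library holds more erythroid cells. For more red cells or reticulocytes, the globin genes and Alas2 gave a median log2 ratio of -0.0133, so as a set they show no rise in replicate 2. Hba-a1 stood at 548 TPM and Hbb-bs at 357 TPM on average. All 5 genes are members of the fixed erythroid list and their ratios had been seen, so this is no separate test. As erythroid list genes, they weigh in the same way on the precursor explanation below. Scaling of the libraries moves all genes alike, and it is argued against by the B cell median of -0.96 and the median of -0.0133 just given beside 1.69 for the erythroid list; the lowest erythroid median over the total, TMM, size factors and ERCC total, 1.61, adds little, since these scalings hardly differ. More nucleated erythroid precursors are a candidate explanation that stays open: the early erythroid list, which shares 0 of its 12 genes with the fixed lists, had a median log2 ratio of 1.17, above every random list, with 7 called, while its most abundant gene, E2f2 (41.8 TPM), stood at 0.03. The late erythroid list lay lower, at a median of 0.19 (percentile 98.86) with 1 of 11 called, the labels name no sort that would remove such cells, and no biological explanation tied to the design was tested.

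Col1a1 and Col1a2 were 3.84-fold and 3.58-fold higher in replicate 2, and Sparc (log2 ratio 1.80) and the osteocalcin gene Bglap (1.77) were higher as well. The fibroblast list had a median of 0.135 TPM in replicate 2, with Col3a1 at 0.13 TPM beside Col1a1 at 96.4 TPM. The bone forming cell list had nearly the same median there, 0.14 TPM. These medians alone therefore cannot tell fibroblasts from bone-forming cells as the source. Col3a1 did not rise with Col1a1, at 11 reads in replicate 1 and 8 in replicate 2. The fibroblast median log2 ratio was 0.51 (percentile 92.78), with 4 ratios above 0 and 4 below. Col5a2 of that list (1.74) was called higher. Dcn (12 and 36 reads) and Lum (0 and 12 reads, at least 4.1-fold) also had more reads in replicate 2. From the second transcript table the log2 ratio was 0.51 for Dcn and 1.83 for Col5a2, and Lum again had none in replicate 1. Col3a1, Col6a1, Col6a2 and Fbln1 stood at -0.39, -0.30, -0.81 and -0.20 there. In fixed lists were 1 of the 10 fibroblast genes and 4 of 8 in the spleen stroma list, whose median was 0 TPM in both libraries. Bone-forming cells may be a source. Of 13 genes of that list, 7 had enough reads, with a median log2 ratio of 1.47 (percentile 99.97). That median met the bound written before the test. In replicate 1, Cgref1, Pcolce, Col22a1 and Smpd3 of these 7 had only 1 to 11 reads. In the second transcript table these 4 had log2 ratios of 1.83, 1.18, 0.29 and 1.24. There Slc36a2 stood at 0.02, Creb3l1 at -0.05 and Ifitm5 at -1.14. The middle value of the 7 there was 0.29, so the median of 1.47 depends on the table. A further demand for 3 genes with 50 reads, added after the gene table values were seen, was not met. Only Slc36a2 (-0.09) and Creb3l1 (0.04) had them, and on that ground the explanation is left undecided here. Ibsp (26 and 33 reads), Alpl (17 and 23 reads), Ifitm5 (18 and 8 reads), Spp1 (105 and 71.8 reads, -0.50) and Runx2 (-0.14) showed no comparable ratio; the spleen is known here from the labels alone, and neither the organ label nor a biological difference was tested.

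Calls on pseudogenes and small RNA genes may come from reads divided differently among near-identical copies. Of 40 such calls, 17.5% were also made in the same direction from the second transcript table, against 76.0% of 217 protein-coding calls, which met the bound of under 0.5 of the calls written before the test. Only 14 of the 40, all pseudogenes, had enough reads in the second table to be tested, and 7 of these 14 were called the same way (exact interval 23.0% to 77.0%) against 79.3% of 208 protein-coding calls, so over testable calls that bound was not met. Fully identical transcripts are argued against as the source, since only 2 of the 40 had such a copy. Nutf2 and Nutf2-ps1 had log2 ratios of -4.31 and 2.40 in the gene table and 0.31 and 0.35 in the second table, and no biological explanation was tested.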
